A study of Phanerodontia chrysosporium with 18 samples.

How the data were processed

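RNA of Phanerochaete chrysosporium RP-78 grown on spruce sapwood sections was sequenced at 40 h and 96 h, per the labels' protocols, from poly-A selected RNA of pools of 20 sections, with 3 pools per time. The submitters' processing notes name CASAVA 1.8.2. The aligner, the read counter, the genome build and the annotation are not given in the sources used here. The deposited table holds 18 columns of RPKM made by the authors, one per library and lane, for 13602 gene models, in which 0.002 stands for no reads. Per the file headers it also holds the authors' mean RPKM per time, the ratio of these means and a p-value with its t statistic. A further column gives a fraction between 0 and 1, the probability of a signal peptide, per the file headers. Each replicate number in the sample titles covers 1 sequencing lane of a time, by the lane in the labels' descriptions, though at 96 h numbers 1 and 3 cover lanes 3 and 1. The barcode number was taken as the library, since each has its own index sequence there, so the 3 lanes of a library were averaged on the linear scale and counted once. Whether the section pools came from separate cultures is stated only as separate samples, and p-values measure the spread between these 6 libraries.

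Gene models with at least 1 RPKM in at least 3 libraries were kept (11725), and 1877 were not tested, of which 638 had no reads in any lane. RPKM as deposited, with no further scaling, was transformed to log2(RPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a variance trend, no block). P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. Before the data were examined, 30 gene lists were fixed as text patterns on the annotation, together with the design, the named genes and the alternatives. Lists with at least 5 tested members were tested with camera at a correlation of 0.01, then with an estimated correlation and with fry. The patterns of 6 lists also matched genes of other functions, and lists without these were made after seeing the data. Shares of summed RPKM used these lists, with the other lists as fixed, and an exact permutation test. The other lists were not refined, and some hold genes of other functions too. Examples are the flavoprotein monooxygenase 3008848 in the respiratory chain list and the splicing factor model 11021 in the oxidant defence list. Named genes are the 8 largest rises and 8 largest falls with an annotated function, among models past the threshold, with all libraries of the times separated and a higher mean above that of the median gene; the 3 largest of each kind without annotation; every tested lignin and manganese peroxidase; and, from each other list, the 2 members with the largest change past the threshold.

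The fits were tested on simulated data with 11725 genes, the real 40 h means and, for each gene, 1 moderated SD used at both times. Genes were drawn independently and few were changed. Unequal spread between the times, correlation between genes and widespread change were therefore not tested. Of 50 genes changed at each size, 44 were recovered at 1.5-fold, 49 at 2-fold, 50 at 4-fold and 50 at 8-fold, with 7 false calls, and 10 simulations with no change gave at most 0 calls.

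Read totals are not given, so no counting interval could be formed. Relative depth was taken from 165 models with no reads in at least 6 lanes, as the ratio of the smallest values above the floor. Of 549 values, 74.3% lay within 0.1 of a whole number of reads, against 20% for evenly spread values. The scale of each library was fitted on the smallest values of the same models, so this share is no independent check. Estimates from alternate models differed by at most 1.1%. The estimate was the third form tried: an earlier choice of models gave fewer whole numbers than chance, and an estimate per lane differed between alternate models, so both were discarded. The median SD on the log2 scale was 0.0597 between lanes of a library, 0.0715 between 40 h libraries and 0.12 between 96 h libraries. No lane columns were identical. Alternatives were the pseudocount, the filter, the scaling, the variance trend, each library left out, a replicate block, the treatment of lanes, the list test and the threshold.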

Results

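Transcripts of the white-rot fungus Phanerochaete chrysosporium, strain RP-78, were measured by RNA sequencing on thin spruce sapwood sections at 40 h and at 96 h after inoculation. White-rot fungi degrade lignin, the aromatic polymer of wood, as well as cellulose and hemicellulose. The agar around the sections held nitrogen and mineral salts and no added carbon source. Each time point had 3 libraries, and each library came from RNA of 20 pooled sections. Every library was sequenced in 3 lanes, so the 18 deposited columns are 6 libraries, and lanes were not counted as replicates. The values are RPKM (read numbers scaled to the length of the gene model and to the reads of the lane) for 13602 gene models, named here by protein number and by the curated function in the table. Read totals are not given in the sources used here. The steps between low RPKM values gave relative depths of 1, 0.72 and 0.948 for the 40 h libraries and 0.48, 0.503 and 0.714 for the 96 h libraries, so low values at 96 h rest on fewer reads.

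The comparison of 96 h with 40 h addresses gene regulation around the start of lignin oxidation, the subject named in the series title; only transcript levels were compared here. Lignin peroxidases, manganese peroxidases, glyoxal oxidase and xylanases were among the largest rises of annotated genes. Aspartic peptidases, a sulfate adenylyltransferase, a sulfate permease and cytochrome b2 were among the largest falls. Of 11725 gene models tested, 7267 (62.0%) changed at an adjusted p below 0.05 in limma's moderated test, 3088 of them higher and 4179 lower at 96 h. Changes of at least 2-fold were found for 979 higher and 876 lower models, and changes of at least 4-fold for 333 higher and 237 lower models. With a pseudocount of 5 in place of 1, 576 were at least 2-fold lower. By P and ratio in the authors' deposited table, a comparison added after seeing the data, 397 were at least 4-fold lower. For 8127 tested models (69.3%) all 3 libraries of one time lay above all 3 of the other, against 10% by chance. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Library 2 at 96 h stood apart from the other 96 h libraries, with correlations across genes of 0.984 and 0.992 to them against 0.995 between those, and without it 7950 models changed.

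**Figure D1:**
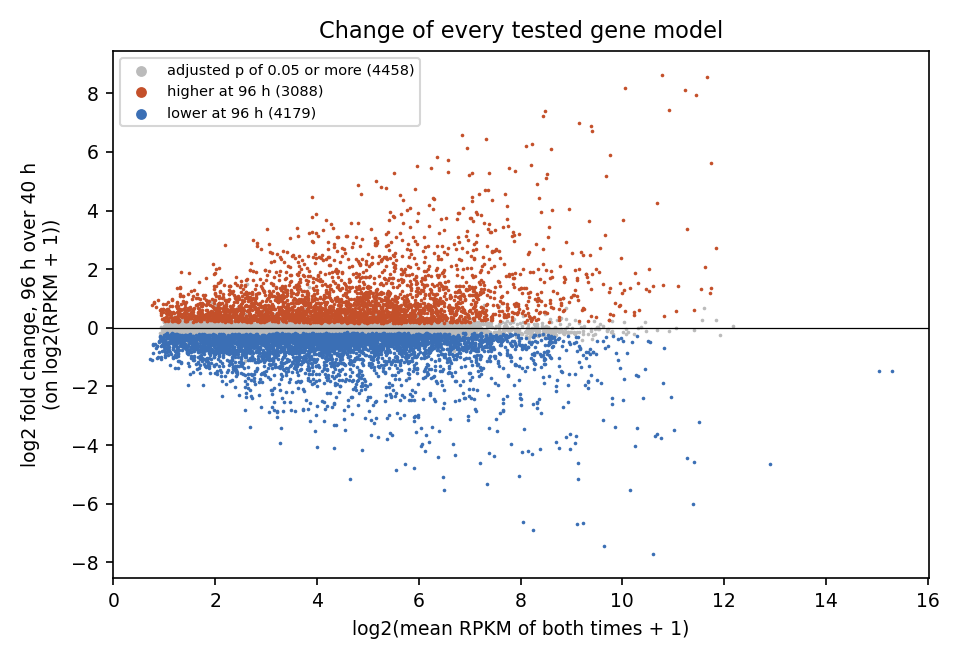
Log2 fold change of each tested gene model, 96 h over 40 h, against the log2 of its mean RPKM plus 1. Each point is a model, coloured by direction where the adjusted p is below 0.05 (3088 higher, 4179 lower) and grey otherwise (4458).

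Lignin peroxidases, heme enzymes that oxidize nonphenolic aromatic units, rose for 9 of the 10 tested genes. LiPD (1386770) went from 7.35 ± 0.582 to 3532 ± 1551 RPKM (SD, n = 3), a log2 fold change of 8.63 (SE 0.28, adjusted p = 2.34e-07). LiPE (1716042) went from 16.2 ± 0.659 to 6467 ± 1334 RPKM and was the most abundant lignin peroxidase at 96 h. LiPB (1716776) rose by 7.38 on the log2 scale, lipG (2918435) by 5.45, LiPA (2989894) by 5.31 and LiPC (3032409) by 4.04. LiPC differed widely among the 96 h libraries, at 46.3, 293 and 106 RPKM in libraries 1, 2 and 3. LiPJ (3043032) reached 20.3 ± 10.2 RPKM at 96 h, LiPI (3032425) 6.84 ± 0.537 and lipF (2910310) 5.61 ± 0.343, with log2 fold changes of 1.64, 1.07 and 0.60. lipH (2918661) did not pass the test, with 17.9 ± 0.796 RPKM at 40 h and 15.4 ± 1.94 at 96 h (adjusted p = 0.0869). Without library 2 of the 96 h group its adjusted p was 0.0057, and over all alternatives it ranged from 0.00237 to 0.280. The list test, camera, gave an adjusted p of 4.34e-05 for the 11 models matched by the list's pattern, one of them a cleft lip domain protein (2898190) that is no peroxidase. The adjusted p = 0.321 with an estimated correlation. How the authors assigned reads shared by similar peroxidase genes is not given in the sources used here, so values of single members are uncertain to that extent.

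Manganese peroxidases, which oxidize Mn(II) to a diffusible oxidant, rose for all 5 tested genes. MnP5 (2971944) went from 15.7 ± 1.47 to 4801 ± 1732 RPKM (log2 fold change 8.09, SE 0.27, adjusted p = 2.39e-07) and mnp1 (8191) from 20.9 ± 2.21 to 5586 ± 1709 RPKM. MnP2 (3589) went from 10.6 ± 3.11 to 1329 ± 114 RPKM. mnp3 (2896529) reached 13.3 ± 3.30 RPKM and MnP4 (2907883) 5.84 ± 1.05, with log2 fold changes of 1.09 and 0.49. Camera gave an adjusted p of 0.00108, and the adjusted p = 0.321 with an estimated correlation. Adjusted over the list alone, 9 lignin peroxidase and 5 manganese peroxidase models passed, as over all genes. Lignin peroxidases took 0.00891% of summed RPKM at 40 h and 1.47% ± 0.300 at 96 h (SD, n = 3), and manganese peroxidases 0.00681% and 1.497% ± 0.426. Library 2 at 96 h had the lowest share of its time for both, 1.19% and 1.01%. The exact two-sided permutation test of these shares gave p = 0.1 for both, the smallest value that 3 against 3 libraries allow.

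**Figure D2:**
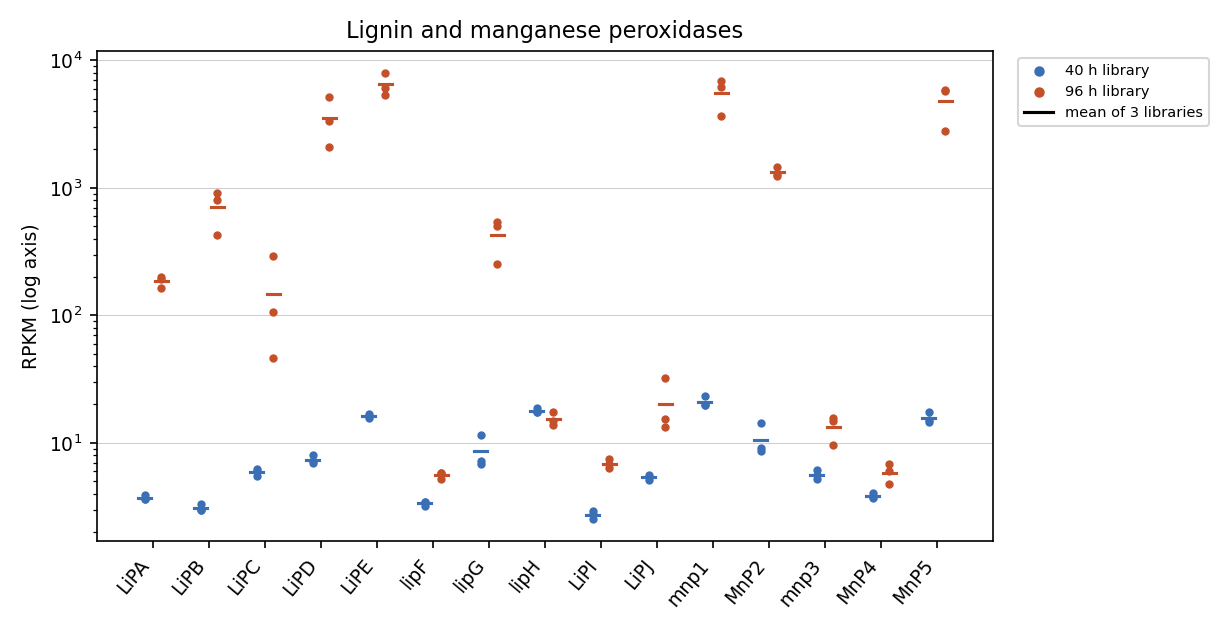
RPKM of each tested lignin and manganese peroxidase on a log axis, with one point per library and a bar at the mean of 3 libraries. LiPE has the highest mean at 96 h, 6467 RPKM, while lipH has means of 17.9 RPKM at 40 h and 15.4 at 96 h, with overlapping points.

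Enzymes that produce hydrogen peroxide, the cosubstrate of these peroxidases, did not move as a list: 10 of 42 tested models rose and 19 fell (camera adjusted p = 0.951). Within it, the copper radical enzyme glyoxal oxidase (11068) went from 21.0 ± 0.854 to 3826 ± 490.2 RPKM (log2 fold change 7.44, SE 0.10). An alcohol oxidase annotated as methanol oxidase (3004321) went from 139 ± 34.3 to 6684 ± 182 RPKM and took 0.852% of summed RPKM at 96 h. The list's share was 0.219% ± 0.0129 at 40 h and 1.45% ± 0.0670 at 96 h, and without the 10 genes of highest mean 0.243% and 0.664% (exact permutation p = 0.1 for both). Of the cellobiose dehydrogenase and lytic polysaccharide monooxygenase genes, 7 of 17 rose and 2 fell (camera adjusted p = 0.140). Without library 2 of the 96 h group this list passed (adjusted p = 0.0351), and over all alternatives its adjusted p ranged from 0.0294 to 0.963. The monooxygenase 2934397 rose by 3.38 on the log2 scale, and 3026777 fell by 1.56 on the log2 scale.

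Genes for hemicellulose breakdown rose together, with 31 of 37 tested models higher and 1 lower. The xylanases xyn10B (2983729) and xyn10D (2935636) went from 3.49 ± 0.176 to 685 ± 139.7 RPKM and from 7.32 ± 0.132 to 1128 ± 433 RPKM. Camera gave an adjusted p of 1.75e-10, and the adjusted p = 0.669 with an estimated correlation. The list took 0.694% of summed RPKM at 40 h, and at 96 h 2.96%, 1.76% and 2.49% in libraries 1, 2 and 3. Pectinases, which cut the pectin of the middle lamella, rose for 6 of 7 models, among them the pectin esterase 2934294 (log2 fold change 4.78) and the GH28 enzyme 2989563 (2.66). Their camera adjusted p was 0.00132, and the adjusted p = 0.905 with an estimated correlation. Of the models matched as cellulases, 18 of 25 rose and 4 fell (camera adjusted p = 0.00305; adjusted p = 0.669 with an estimated correlation). The cellobiohydrolase cel7D (137372) went from 549 ± 109 to 2406 ± 1305 RPKM, and the GH5_9 enzyme 2915237, which shares the domain but has another specificity, from 519.6 ± 13.4 to 86.1 ± 19.6 RPKM. Without members of other specificities 12 of 15 rose and 1 fell (camera adjusted p = 0.000897; adjusted p = 0.620 with an estimated correlation). Beta-glucosidases went both ways, with 5 of 14 higher and 4 lower (camera adjusted p = 0.839). The beta-xylosidase-like 2919526 and the glucan 1,3-beta-glucosidase exg55A (3006885) rose by 2.78 and 2.71 on the log2 scale.

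Major facilitator and sugar transporters rose for 65 and fell for 38 of 151 models (camera adjusted p = 0.00305; adjusted p = 0.444 with an estimated correlation). The transporters 2989142 and 3025694 went from 1.42 ± 0.304 to 227 ± 14.2 RPKM and from 6.33 ± 0.368 to 542 ± 37.2 RPKM. Other groups linked to the handling of aromatic compounds changed in both directions without passing camera. With fry, which tests each list on its own, glutathione S-transferases (adjusted p = 0.00649) and quinone and aryl alcohol reductases (0.00292) passed. Cytochrome P450 (0.0625) and ABC transporters (0.0521) did not pass fry. Of 148 cytochrome P450 monooxygenase models 58 rose and 51 fell (camera adjusted p = 0.232), and 3029010 went from 20.1 ± 7.91 to 698 ± 43.3 RPKM. Of 26 glutathione S-transferases 12 rose and 9 fell (adjusted p = 0.157), with a log2 fold change of 3.53 for 2903766. Of 66 models matched as quinone and aryl alcohol reductases 26 rose and 18 fell (adjusted p = 0.232). An aryl alcohol dehydrogenase (11055) went from 63.5 ± 13.6 to 691 ± 20.4 RPKM. Of the 66, 54 carried an aldo/keto reductase domain, among them a xylose reductase (3030943), and 7 were NADH-ubiquinone oxidoreductase models of the respiratory chain. Without these 7, a list made after seeing the data, 26 of 59 rose and 13 fell (camera adjusted p = 0.0596). ABC transporters rose for 10 and fell for 21 of 51 models (adjusted p = 0.408), and 135309 fell by 2.49 on the log2 scale.

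The 8 annotated models with the largest falls were 4 aspartic peptidases, sulfate adenylyltransferase, a sulfate permease, cytochrome b2 and a ribonuclease. The aspartic peptidase asp1 (3030626) went from 1093 ± 220.2 to 9.60 ± 1.23 RPKM (log2 fold change -6.68, SE 0.15, adjusted p = 5.22e-08). A second family A1 peptidase (2915771) had a log2 fold change of -6.64 from 1191 ± 40.0 RPKM at 40 h, Asp2 (2919778) one of -5.54 and 2903097 one of -5.34. The protease list as a whole was split, with 75 of 251 models higher and 82 lower (camera adjusted p = 0.612). Its share of summed RPKM was 5.74% ± 0.574 at 40 h and 3.39% ± 0.151 at 96 h, and without the 10 genes of highest mean 6.25% and 3.10% (exact permutation p = 0.1 for both). Sulfate adenylyltransferase (2484321), which activates sulfate, went from 527 ± 120.5 to 4.28 ± 0.723 RPKM, and a sulfate permease (2965237) from 176 ± 36.0 to 2.83 ± 0.53 RPKM. Cytochrome b2 (3030467), a lactate dehydrogenase in yeast, went from 5305 ± 514 to 84.2 ± 31.5 RPKM, and the ribonuclease RNase U2 (2913961) from 1096 ± 205 to 29.8 ± 4.64 RPKM. Among nitrogen acquisition genes 9 of 52 rose and 22 fell (camera adjusted p = 0.232, fry adjusted p = 0.0426). A permease for purines and related bases (2911559) fell by 3.58 on the log2 scale. Oligopeptide transporters did not pass as a list (6 of 16 higher, 3 lower, adjusted p = 0.329), though 2969194 had a log2 fold change of -3.70 from 1009.9 ± 34.4 RPKM at 40 h.

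**Figure D3:**
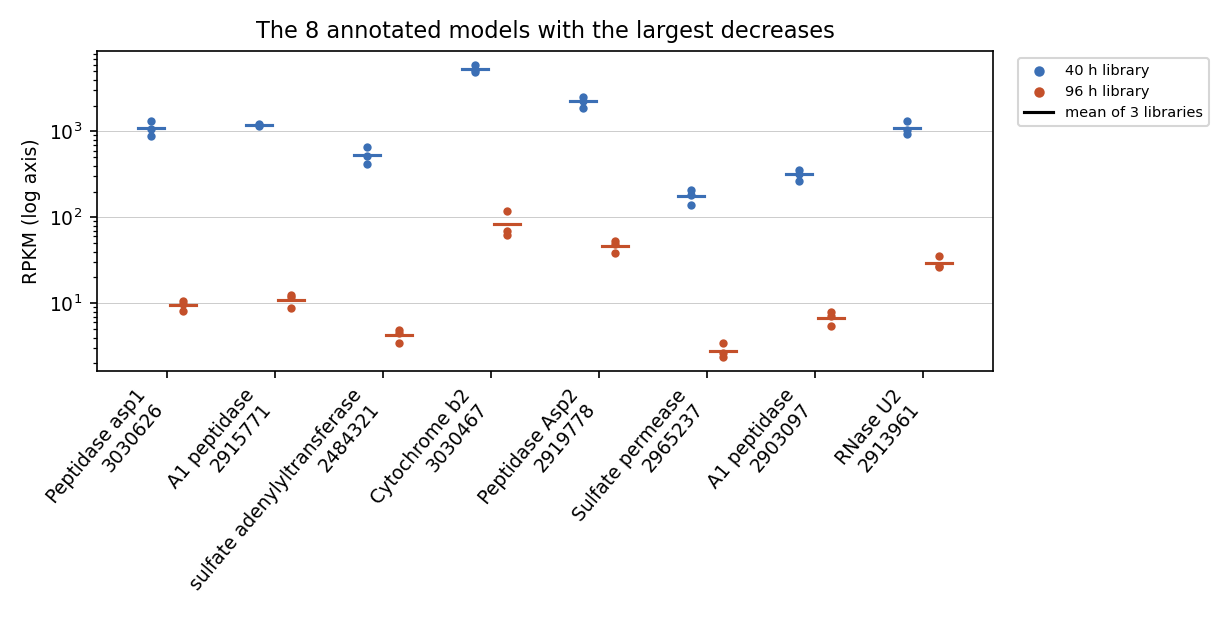
RPKM on a log axis of the 8 annotated models with the largest falls under the naming rule, with one point per library and a bar at the mean of 3 libraries. In each model all 40 h points lie above all 96 h points, which the naming rule required.

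Genes with no annotated function were also among the largest changes. Models 1602550, 3001697 and 3027627 rose by 8.18, 6.44 and 6.27 on the log2 scale. Models 1681886, 8648 and 3032475 had log2 fold changes of -7.71, -7.43 and -6.90, with 1681886 going from 3104 ± 497 to 14.0 ± 3.51 RPKM.

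Genes for fungal cell wall synthesis and turnover fell for 34 of 45 models and rose for 5. The chitinase family GH18 model 2985660 went from 953 ± 179.5 to 53.3 ± 3.20 RPKM and the GH18 fragment 3024580 had a log2 fold change of -3.52. Camera gave an adjusted p of 4.34e-05, and the adjusted p = 0.669 with an estimated correlation. Respiratory chain genes fell for 21 of 29 models and rose for 1 (camera adjusted p = 0.00108; adjusted p = 0.922 with an estimated correlation). A cytochrome c oxidase subunit (3023358) and a fumarate reductase (123932) had log2 fold changes of -3.88 and -2.37. The fumarate reductase was matched by a domain name that it shares with succinate dehydrogenase. Ribosomal protein genes fell for 40 of 123 models and rose for 3, by small amounts, with a median log2 fold change of -0.17 (camera adjusted p = 0.0141; adjusted p = 0.963 with an estimated correlation). That call was also lost without library 2 of the 96 h group (adjusted p = 0.360), after trimmed-mean scaling (adjusted p = 0.0585) and with fry (adjusted p = 0.0648), and over all alternatives the adjusted p ranged from 0.000232 to 0.963. Of all 11725 tested models 4179 fell and 3088 rose, with a median log2 fold change of -0.0786. The ribosomal list thus stood out by few rises, not by many falls. The ratio of its share of summed RPKM, 96 h over 40 h, was 0.984 (exact permutation p = 0.9). Without the 10 genes of highest mean this ratio was 0.908 (exact permutation p = 0.2). Glycolysis genes fell for 10 of 18 models and rose for 2 (camera adjusted p = 0.0915), with log2 fold changes of -2.43 for phosphoglycerate mutase (2981615) and -1.96 for pyruvate kinase (1303762). Without library 2 of the 96 h group this list passed (adjusted p = 0.0461), and over all alternatives its adjusted p ranged from 0.00932 to 0.963.

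**Figure D4:**
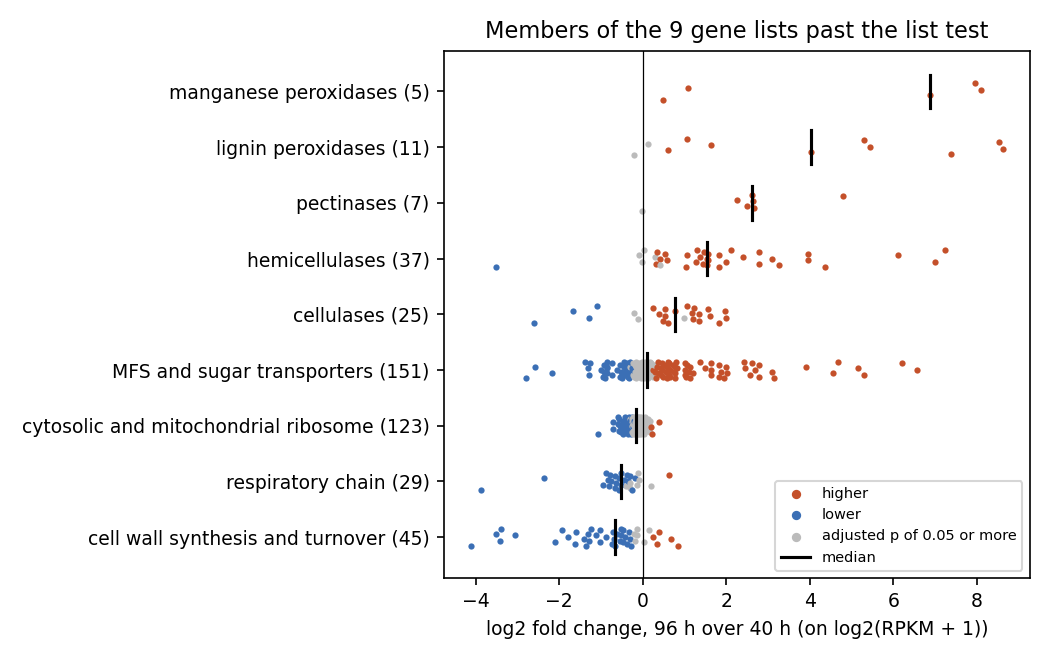
Log2 fold change, 96 h over 40 h, of each tested member of the 9 gene lists past the list test, with the number of tested members in parentheses and a bar at the median. Coloured points have an adjusted p below 0.05; manganese peroxidases have a median of 6.87 and cell wall genes one of -0.67.

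The remaining lists did not pass camera. With fry, iron and copper (adjusted p = 0.0184), oxidant defence (0.00921), lipid (0.0270), hydrophobin (0.0108) and spore and mating genes (0.00544) passed, and the others did not. Proteasome and ubiquitin genes rose for 18 and fell for 40 of 100 models, chaperones for 15 and 27 of 70, iron and copper genes for 9 and 12 of 27, and oxidant defence genes for 14 and 7 of 27. Genes of glyoxylate, oxalate and formate metabolism rose for 5 and fell for 6 of 14. Of 6 oxalate decarboxylase models 1 rose and 3 fell. One (2907675) went from 2.47 ± 0.381 to 187 ± 62.4 RPKM, and another (2969988), chosen after its values were seen, from 190.3 ± 35.7 to 11.1 ± 0.892 RPKM. A model annotated as carboxyphosphonoenolpyruvate phosphonomutase (3006287) had a log2 fold change of -4.64 from 14803 ± 1496 RPKM at 40 h. Lipid genes rose for 22 and fell for 21 of 60 models, hydrophobins, small surface proteins of fungi, for 8 and 10 of 20, and spore and mating genes for 2 and 6 of 9. Of the hydrophobins 8 were at least 2-fold higher and 4 at least 2-fold lower. The hydrophobin share of summed RPKM was 0.0702% at 40 h and 0.289% at 96 h (exact permutation p = 0.1). Transcription factor models rose for 87 and fell for 79 of 326. The list of cell cycle and replication genes rose for 51 and fell for 73 of 190 models, and 139 of these, nearly all F-box proteins matched by their domain name, are of other functions. Without them, 7 of 51 rose and 31 fell (camera adjusted p = 0.0216; adjusted p = 0.929 with an estimated correlation). For 9 of the 30 lists the median, the mean and the camera test differed in sign, and none of the 9 passed camera.

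In all, 9 of 30 lists passed camera with a preset correlation of 0.01, 6 of them higher and 3 lower. With correlations estimated from the data none passed, and 3 had an unadjusted p below 0.05; with fry, which tests each list on its own, 18 passed. At 9 lists, 2 other divisions of the 6 libraries into 3 and 3 gave as many as the division by time. Those divisions hold both times in unequal numbers, so part of the change with time remains in them. Their counts therefore do not measure chance. Adjusted over the list alone, the counts higher and lower were 32 and 1 for hemicellulases, 65 and 39 for major facilitator transporters, 1 and 22 for the respiratory chain and 1 and 34 for ribosomal proteins. They were 10 and 20 for peroxide-producing oxidases, 75 and 84 for proteases, 15 and 7 for oxidant defence, 22 and 22 for lipid genes, 51 and 76 for the cell cycle and 82 and 72 for transcription factors. In all other lists these counts equalled those over all genes.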

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

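The block by column-name numbers, the lane average on the log2 scale, the lists without members of other functions and the authors' own calls were alternatives chosen after seeing the data. All 83 named genes kept their direction under every alternative that tested them, and 1491 of 1493 values kept their side of the threshold. The exception, lipH (2918661), passed without 96 h library 2 and with lanes treated as replicates. Apart from the lignin and manganese peroxidases, these genes were chosen for large changes in the same libraries. For them this result was therefore nearly fixed in advance. Leaving out one library in turn gave 6094 to 7950 changed genes, 307 to 344 at least 4-fold higher and 226 to 256 at least 4-fold lower, and 9 to 10 lists. The count of genes at least 2-fold lower was 576 with a pseudocount of 5, which shrinks low genes by construction. By the authors' deposited P and ratio over all models, 397 were at least 4-fold lower, against 237 in the main fit. That ratio is of mean RPKM with no pseudocount, and with a pseudocount of 0.1 in place of 1 the count was 302. The models covered and the P also differ, and these parts were not told apart. Counting lanes as replicates gave 9315 changed genes. No list passed camera with estimated correlations (0 lists) and 18 passed fry. The estimated correlation of every list lay above the preset 0.01, from 0.0159 for major facilitator and sugar transporters to 0.897 for pectinases. It was 0.341 for hemicellulases. The camera p-values at the preset thus rest on a lower correlation than these estimates, which come from 6 libraries. The form of fry that ignores direction passed all 30 lists. How far this accounts for the counts was not tested. Among single lists 12 calls were lost and 14 gained, and the ribosomal list was lost most often. Higher genes made up 42.5% of calls as deposited and 49.4% after trimmed-mean scaling. The labels number the libraries in 2 ways, and neither numbering paired them. By barcode, deviations of same-numbered libraries correlated at 0.136, 0.133 and -0.102. By the numbers in the column names, 40 h library 1 goes with 96 h library 3 (0.218), 2 with 1 (-0.0971) and 3 with 2 (0.0757). Under neither did every library correlate best with its own number. A replicate block by barcode gave 7121 changed genes and one by column names 7024, and neither changed a list's call. Depth limits low genes, and 96 h libraries 1 and 2 were the shallowest. The relative depth of 96 h library 3 (0.714) was close to that of 40 h library 2 (0.72).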

Other observations

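The lists, families and named genes in this part, and all of its tests except the counts over other splits of the libraries, were chosen after the result was seen. O-methyltransferases rose for 9 and fell for 3 of 14 tested models (camera adjusted p = 0.00313; adjusted p = 0.339 with an estimated correlation). Model 2661209 went from 10.4 ± 2.19 to 768 ± 33.0 RPKM (SD, n = 3) and 2974896 from 18.7 ± 6.68 to 712 ± 79.3 RPKM. Genes that regenerate the methyl donor S-adenosylmethionine rose for 5 and fell for 1 of 7 models (camera adjusted p = 0.00946; adjusted p = 0.339 with an estimated correlation). Adenosylhomocysteinase (3010314) went from 294 ± 34.3 to 1053 ± 59.7 RPKM and a model with an S-adenosylmethionine synthetase domain (3000973) rose by 1.98 on the log2 scale. Ribonucleases and S1/P1 nucleases fell for 4 and rose for 1 of 6 models (camera adjusted p = 0.04; adjusted p = 0.339 with an estimated correlation), among them rnt1 (2915412), from 775 ± 22.6 to 52.3 ± 10.9 RPKM. The aspartic peptidases of family A1 were split, with 23 of 56 lower and 15 higher (camera adjusted p = 0.401). Asp4 (2917955) and asp3 (3031920) rose by 3.29 and 4.42 on the log2 scale while asp1 and Asp2 fell.

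Among 137 domain families with at least 8 tested members, 13 passed camera, 9 higher and 4 lower; with estimated correlations none passed and 3 had an unadjusted p below 0.05. Core histones fell for 13 of 16 models, kinesins for 9 of 10 and subunits of the 20S proteasome for 14 of 14. Fungal cellulose-binding regions rose for 10 of 11 models, proteins with a poly(ADP-ribose) polymerase catalytic region for 8 of 9 and a conserved hypothetical family, CHP02464, for 9 of 12. With each scaling these directions held. Further lists without genes of other functions did not pass: ABC transporters (10 of 46 higher, 19 lower, camera adjusted p = 0.612), quinone and aryl alcohol reductases (26 of 59 higher, 13 lower, 0.0596) and fatty acid oxidation (5 of 21 higher, 9 lower, 0.789). Proteins with a predicted signal peptide (probability above 0.9) were split, with 362 of 1015 higher and 383 lower (camera adjusted p = 0.416). A pair of hypothetical models, 3014073 and 2891358, took 6.99% and 5.86% of summed RPKM at 40 h and 2.89% and 2.42% at 96 h.

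In a list around sulfate uptake and activation 8 of 13 models fell and 2 rose, against 5 higher and 1 lower of 7 in the methyl cycle. Camera gave the sulfate list an adjusted p of 0.0299, and the adjusted p = 0.339 with an estimated correlation. The list holds the sulfate adenylyltransferase and the sulfate permease already named among the largest falls, so its test is no separate support. Members outside uptake and activation include a phosphoadenosine phosphosulfate reductase (1738362), a sulfite efflux pump (2906511, log2 fold change -5.10) and a bisphosphate nucleotidase (2918498, -4.21). Adenylylsulphate kinase (2906513) went from 927 ± 182 to 74.4 ± 19.2 RPKM. Reads of one gene copy counted for another would keep the sum over copies. The summed RPKM of the 2 ATP sulfurylase models went from 613 ± 108 to 148 ± 25.7, a ratio of 0.241. That argues against such an exchange between these 2 models, although one of them (2434212) rose, with a log2 fold change of 0.72. The other genes of the list were not tested for it. A fall of every step to sulfide is argued against by the model annotated as sulfite reductase (2898942), which rose, with a log2 fold change of 1.35 (SE 0.08); 2 further models with a nitrite and sulphite reductase region, 3011231 and 2977351, did not pass (log2 fold changes -0.09 and 0.30, adjusted p = 0.705 and 0.0933). No biological explanation was tested.

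Library 2 at 96 h lay nearer the 40 h libraries, with correlations across genes of 0.886 to 0.897 to them against 0.869 to 0.883 for the other 96 h libraries. In 331 models raised at least 4-fold in the other 96 h libraries, it lacked a median of 18.9% of the rise (quartiles 1.2% and 39%). RNA of 40 h samples mixed in would leave the same share of the fall missing, but in 49 models lowered at least 16-fold that share was a median of 0.895% (quartiles 0.176% and 1.46%), which argues against mixing. Lower depth is argued against by its depth relative to 96 h library 1, 1.05. No biological explanation was tested, and a difference in colonization between section pools stays open.

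The authors' deposited table has a P below 0.05 for 10366 models, 9975 of them among the tested ones, and 2759 of these had an adjusted p of 0.05 or more between libraries. A moderated test on the 3 lane means of each time followed the deposited t statistic with a median absolute difference of 0.286, against 7.41 for a test on the 3 library means. This is consistent with lanes having been used as replicates in that table, in which case its P measures the spread between sequencing lanes. The comparison covered 11725 models, and the authors' procedure itself is not given in the sources used here.

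The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Each other split puts libraries of both times in each group, so the change with time widens the spread within its groups. Few gene calls in those splits follow from this, so the gene counts cannot test chance. Only 1 split, that by time, gave as many changed genes, 7267 against at most 0 in the others by limma (at an unadjusted p below 0.05, 7722 against at most 187). The counts higher and lower, at any size, were likewise 0 in the other splits (against 3088 and 4179, 979 and 876, 333 and 237). For lists past camera, 3 of the 10 splits gave 9 or more, the highest other being 9. For domain families, the split by time gave 13 and the highest other 11. The other splits hold both times in unequal numbers, so part of the change with time remains in them. Camera compares the genes of a list with all others and can pick up that part. The list and family counts therefore cannot test chance either.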
